A study of Mus musculus with 12 samples.

How the data were processed

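The series holds RNA-seq of mouse embryos. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Mini Kit and polyadenylated RNA was selected with the NEBNext magnetic isolation module. The values used here are whole-number read counts per gene, deposited by the authors as 1 table of 36255 genes and 11 libraries with no normalization applied. Reads were trimmed with Trim Galore 0.6.7 and the genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool and the use of strand are not given in the sources used here, so counts of overlapping and antisense genes are uncertain. The same holds for genes with near-identical copies, which include H3f3c, Hmga1b, Zfp968, Zfp969, Cd1d2, Apol7b, Smok2b and the globin genes Hbb-bt and Hbb-bs.

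Libraries were grouped by title into 6 groups: Skp1aKO, Skp1acont and Skp1acont PI at 9.5 days post coitum (dpc), wt at 9.0 dpc, wt at 9.5 dpc and wt PI at 9.5 dpc. Each group has 2 libraries except Skp1acont PI, of which 1 library was analysed here and the other of the 12 labelled libraries was not. The labels do not spell out "cont", "PI", "lot" or the "mb" of the titles, and these words are used as written. The source of the samples is embryo while the series text speaks of ES cells or embryoid bodies, so the part of the embryo sampled is not known here. The labels do not say whether the libraries of a group came from separate embryos, so p-values measure the spread between these libraries, which may be technical. Total counts ranged from 2320599 to 11607085 per library. With 3 counts taken as the limit that a count of 0 allows, this gives floors per library from 0.258 to 1.29 CPM, the usual depth-scaled count. Intervals and floors cover counting error only.

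Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group, which left 18837 genes. Libraries were scaled with TMM, and the quasi-likelihood F test was run with robust dispersion estimates in 1 fit of all 6 groups. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. All tests of genes are two-sided. The lone Skp1acont PI library, and any group brought to 1 library by leaving the other out, is assumed to vary like the libraries of the other groups. CPM values are TMM-scaled, and group values are given as mean ± SD. Log2 fold changes are given with their standard error. The tests, the samples in each fit, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

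Alternatives fixed at the same time were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, the lot number as a replicate block, the legacy quasi-likelihood method without robust estimates, a fit of only the groups compared, and leaving out each library of the compared groups in turn. Several alternatives were added after the data were seen. They are fits of the 6 wt libraries alone, with and without the lot as a block, fits without Skp1acont replicate 2 for comparisons that do not use it, library totals in place of TMM, a background rate as a covariate and the background subtracted from the counts. The fit of the 6 wt libraries tested 13126 genes. The biological coefficient of variation was 35.3% in the fit of all groups and 19.4% in the fit without Skp1acont replicate 2. In the fit of the wt libraries it was 19.6%, and 7.19% with the lot as a block. The background rate of a library was the median CPM per kb of exon over 1509 olfactory, vomeronasal and taste receptor genes, which embryos of this age are not known to use. Exon lengths and gene positions came from the GENCODE M21 annotation of GRCm38.

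The lot number was checked as a pairing of libraries before calls were compared. Deviations from the group mean correlated between libraries of the same lot in all 3 pairs of wt groups, with r from 0.297 to 0.343 across genes. In the 7 pairs of groups that include a Skp1a label, r ran from -0.01 to 0.18. The lots were therefore taken as pairing the wt libraries, from the data and not from a statement in the labels.

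Gene lists of pathways, complexes and cell types, 32 in number with 658 genes, were tested with camera and fry of limma 3.58.1 on log2 CPM with a prior count of 2. Camera compares a list with the other genes and was run with its preset and with an estimated correlation between genes. Fry asks whether the genes of a list move, on balance, one way, and compares the list with no other genes. P-values of lists were adjusted over the lists. Agreement in direction between comparisons that share no library was measured as the correlation of log2 fold changes across genes, and tested with fry on the genes called in the first comparison, each signed by its direction there. Genes are not independent replicates.

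The genes named are Skp1a, Ezh2, Eed, Suz12 and Meis2 in every comparison, then up to 6 genes per direction with the largest fold changes among those called, with at least 5 CPM in the higher group and no overlap between libraries, and up to 4 members of each list described, by smallest p. For the difference of the PI effects up to 3 genes per direction were taken. A few genes that this rule selects are not reported here. Where no gene was called, up to 6 genes with small p are given as values, and these need not include the smallest p of all genes. The same rule was applied to the fit of the 6 wt libraries after the data were seen. Where a group had no count of a gene, the fold is given as a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% binomial interval.

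The fits were tested on simulated counts with the means and library sizes of these libraries and 200 genes changed, 100 by 2-fold and 100 by 4-fold. For PI against no PI in wt, the fit of all groups recovered 3% of the 2-fold and 28% of the 4-fold changes, with 3 false calls among 17648 genes, and the fit of the wt libraries recovered 39% and 88%, with 18 false calls among 12820 genes. For the stage comparison the fit of all groups recovered 1% and 28%, with 5 false calls among 17474 genes, and the fit of the wt libraries 34% and 84%, with 24 false calls among 12801 genes. For Skp1aKO against Skp1acont the fit of all groups recovered 0% and 25%, with 3 false calls among 17606 genes, and the fit without Skp1acont replicate 2 recovered 6% and 53%, with 21 false calls among 15982 genes. For Skp1aKO against wt it was 0% and 10%, with 1 false call among 17448 genes, and for PI against no PI in Skp1acont 0% and 6%, with 1 false call among 17391 genes. Set against the calls made, false calls were in each simulation a larger share than the threshold on the adjusted p allows. In the fit of all groups this rests on few calls. The threshold was thus not held in these simulations. Counts of calls given below, and those of the fits added later in particular, may hold more false calls than it allows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.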

Results

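Gene expression was measured by poly(A) RNA-seq in 11 libraries of mouse embryos, as whole-number read counts per gene. Skp1a encodes the adaptor subunit of SCF ubiquitin ligases, and the series concerns its part in the turnover of PRC2, the Polycomb complex that methylates histone H3 and keeps developmental genes silent. The groups were Skp1aKO at 9.5 dpc (n = 2), Skp1acont at 9.5 dpc (n = 2), Skp1acont PI at 9.5 dpc (n = 1), wt at 9.0 dpc (n = 2), wt at 9.5 dpc (n = 2) and wt PI at 9.5 dpc (n = 2). Total counts were 3601338 and 3017451 for Skp1aKO, 4203553 and 2320599 for Skp1acont and 4128267 for Skp1acont PI. They were 4007663 and 11607085 for wt at 9.0 dpc, 3392251 and 9217568 for wt at 9.5 dpc, and 3632898 and 11190592 for wt PI, so that lot 2 was the deeper of each wt pair.

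The 5 libraries with a Skp1a label and the 6 wt libraries differed in the makeup of their counts. Mitochondrial genes took 5.98% to 15.8% of the counts in the former and 2.44% to 4.01% in the latter, and Dock10, a guanine nucleotide exchange factor gene, took 4.48% to 12% against 0.532% to 2.27%. Ribosomal protein genes took 3.10% to 8.56% against 12.1% to 15.4%. The background rate over chemoreceptor genes was 7.14 and 9.31 times the lowest library in Skp1aKO, 3.10 and 14.6 times in Skp1acont, 3.27 times in Skp1acont PI and 1 to 1.75 times in the wt libraries. Log2 CPM correlated across genes with r = 0.966 between the Skp1aKO libraries, 0.795 between the Skp1acont libraries and 0.976 to 0.980 within the wt groups. Skp1acont replicate 2 had the lowest total, the highest mitochondrial share and the highest background of all libraries.

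**Figure D1:**
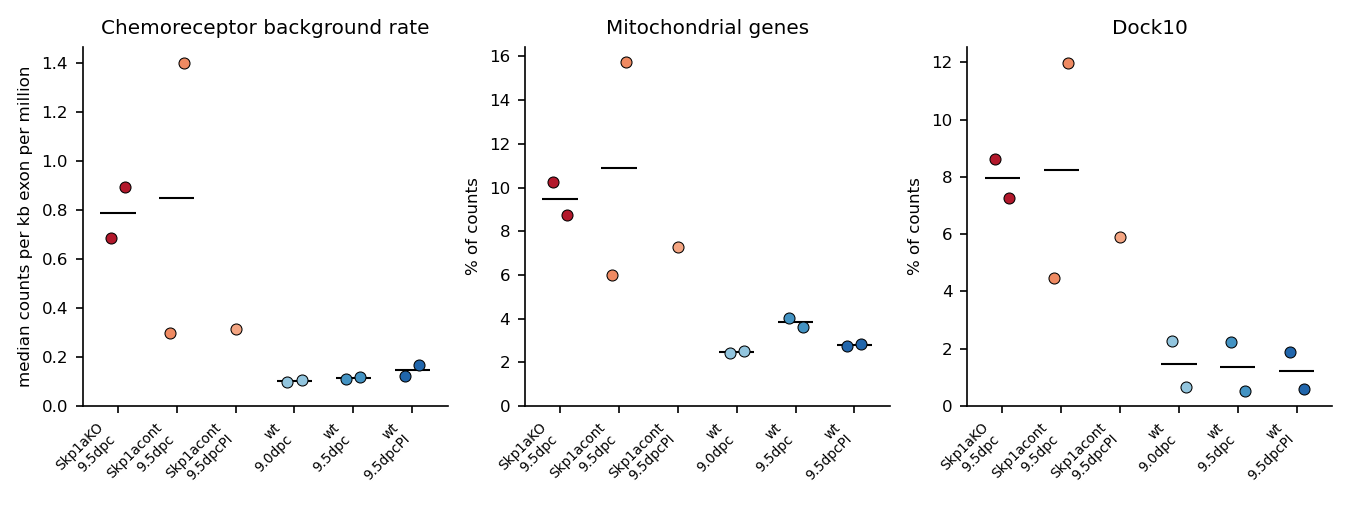
Background rate over chemoreceptor genes (median CPM per kb of exon), mitochondrial share (% of counts) and Dock10 share (% of counts) of each library (points) in the 6 groups, with lines at the group means. Skp1acont replicate 2 has the highest mitochondrial share, 15.8%, and the wt libraries lie between 2.44% and 4.01%.

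The targeted gene was examined first. Skp1a (ENSMUSG00000036309.14, GRCm38 chromosome 11, 52231995 to 52246858) had 199 and 212 CPM in the libraries labelled Skp1aKO, 303 and 104 CPM in Skp1acont, 273 CPM in Skp1acont PI, 1209 and 1337 CPM in wt at 9.0 dpc, 930 and 1136 CPM in wt at 9.5 dpc, and 1180 and 1261 CPM in wt PI. The values of the libraries labelled Skp1aKO lay between those of the Skp1acont libraries, so the Skp1a count did not separate these labels (log2 fold change 0.01 ± 0.51, adjusted p = 1). Counts over the whole gene do not show whether part of it was deleted, and Skp1aKO is used here as a label only. Ezh2, Eed and Suz12, the core PRC2 genes, also had fewer CPM in each of the 5 Skp1a-labelled libraries than in any wt library under TMM scaling. Ezh2, the catalytic subunit (ENSMUSG00000029687.16, chromosome 6, 47530139 to 47595341), had 162 ± 8.95 CPM in the libraries labelled Skp1aKO, 147 ± 93.4 CPM in Skp1acont and 455 ± 12 CPM in wt at 9.5 dpc (n = 2 each). Eed (ENSMUSG00000030619.9, chromosome 7, 89954654 to 89980983) had 35.7 ± 4.48, 41.4 ± 14.2 and 135 ± 11.3 CPM in these groups. Suz12 (ENSMUSG00000017548.15, chromosome 11, 79993106 to 80034123) had 75.2 ± 8.27, 45.9 ± 38.8 and 182 ± 16.4 CPM. Meis2, a homeobox gene and Polycomb target of the midbrain (ENSMUSG00000027210.20, chromosome 2, 115863064 to 116065839), had 86.6 ± 5.93, 105 ± 46.3 and 190 ± 9.60 CPM.

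**Figure D2:**
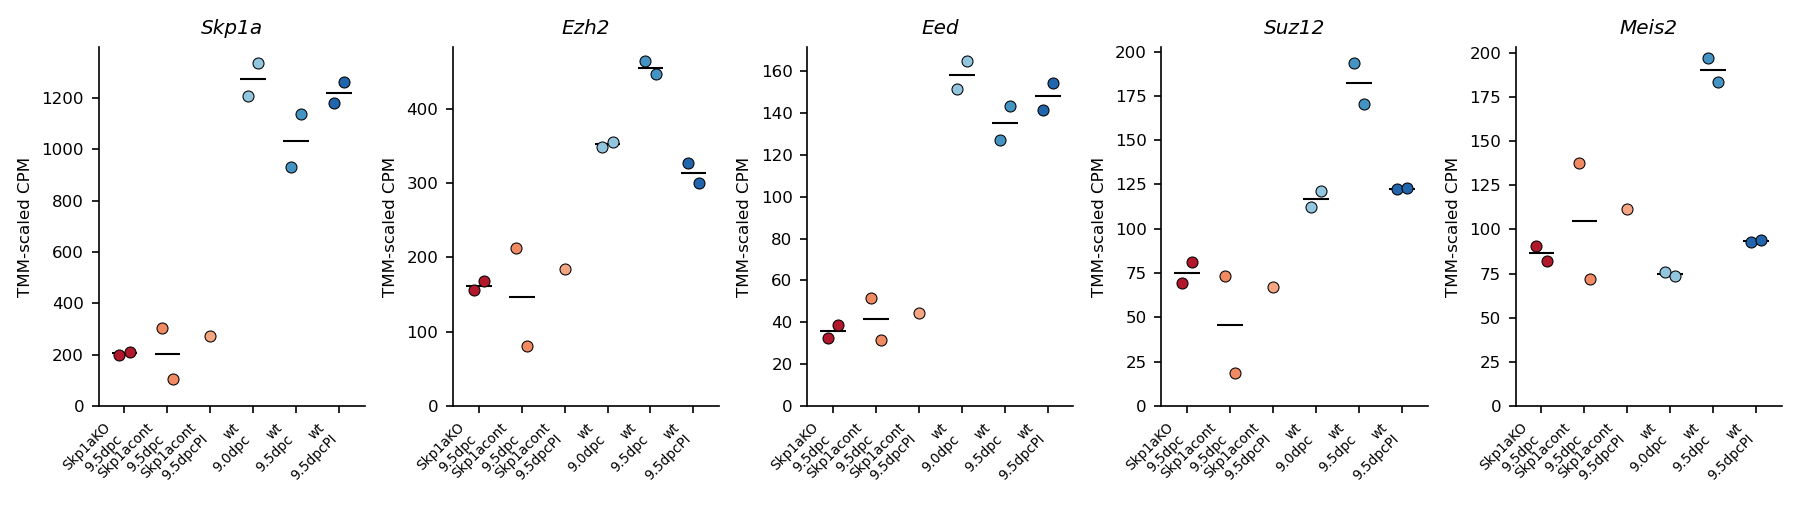
TMM-scaled CPM of Skp1a, Ezh2, Eed, Suz12 and Meis2 in each library (points) of the 6 groups. Skp1a lies between 104 and 303 CPM in the libraries with a Skp1a label and between 930 and 1337 CPM in the wt libraries.

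The comparison of the libraries labelled Skp1aKO with Skp1acont addresses how these labels differ at 9.5 dpc, with Skp1a itself not called between them. Ezh2 differed by 0.14 ± 0.46, Eed by -0.22 ± 0.34, Suz12 by 0.70 ± 0.52 and Meis2 by -0.28 ± 0.36 on the log2 scale, none of them past the test (adjusted p from 0.928 to 1). The smallest adjusted p over all genes was 0.0824, and no gene named for this comparison had it. Some genes with an adjusted p of 0.206 had lower counts in the libraries labelled Skp1aKO, such as Zdhhc12 (2.72 ± 0.0938 against 11.2 ± 0.860 CPM), Yif1a (2.92 ± 1.63 against 17.8 ± 5.98 CPM) and Zfp667 (1.41 ± 0.430 against 14 ± 8.79 CPM). Foxa1, with the same adjusted p, was higher (log2 fold change 2.87). No member of the 40 tested Polycomb-target developmental regulators was called over all genes. Adjusted over the list alone, 2 were higher, Foxd1 (11.3 ± 3.63 against 2.95 ± 0.949 CPM) among them, and camera gave adjusted p = 0.371. Of the 13 tested PRC2 genes 0 were called, and 0 when adjusted over the list alone (camera adjusted p = 0.432). The Hedgehog and ventral list was the first of 3 called by camera, upward, with no member of 13 called over all genes and 1 higher adjusted over the list alone (adjusted p = 3.35e-05, adjusted p = 0.512 with an estimated correlation). The endothelial list went downward, with 0 of 14 called and 3 lower adjusted over the list alone (camera adjusted p = 0.000656, adjusted p = 0.97 with an estimated correlation), and the neural progenitor list upward, with 0 of 16 called (adjusted p = 0.0172, adjusted p = 0.976 with an estimated correlation).

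Across all 18837 genes the edgeR test called 0 between the libraries labelled Skp1aKO and Skp1acont. At an unadjusted p under 0.05 there were 1308 genes, and DESeq2 called 95, of which 24 were higher. The count of 0 was lost when either Skp1acont library was left out. With Skp1acont replicate 2 left out, 4650 genes were called, 1667 higher and 2983 lower, and without Skp1acont replicate 1 it was 5723, with 3877 higher and 1846 lower. Each of these fits holds 1 Skp1acont library, and its spread is borrowed from the other groups, so the p-values do not show how far Skp1acont libraries vary. In the fit without Skp1acont replicate 2, 8 of 35 Polycomb-target regulators were higher and 1 lower, including Foxd1 (log2 fold change 2.32 ± 0.42) and Foxc2 (2.59 ± 0.58). Adjusted over the list alone, 8 were higher and 1 lower (camera adjusted p = 0.0058, adjusted p = 0.571 with an estimated correlation). Of 13 Hedgehog and ventral genes 6 were higher and 0 lower, of 14 endothelial genes 10 were lower and 0 higher, and the neural progenitor list turned downward (camera adjusted p = 0.647). Meis2 was lower by that fit (-0.65 ± 0.20, adjusted p = 0.0195), and Skp1a was not called (-0.55 ± 0.21, adjusted p = 0.0544). The background rate of Skp1acont replicate 1 was 3.10 times the lowest library against 7.14 and 9.31 times in the libraries labelled Skp1aKO.

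The comparison of the libraries labelled Skp1aKO with wt at 9.5 dpc addresses how these labels differ from wild type. Skp1a was lower (log2 fold change -2.33 ± 0.54, adjusted p = 0.0133), and so were Eed (-1.92 ± 0.35, adjusted p = 0.00652), Ezh2 (-1.49 ± 0.47, adjusted p = 0.0346) and Meis2 (-1.14 ± 0.37, adjusted p = 0.0376), while Suz12 did not pass (-1.28 ± 0.53, adjusted p = 0.0778). Scaled by library totals, Skp1a (-1.52, adjusted p = 0.029) and Eed (-1.11, adjusted p = 0.0204) stayed called, and Ezh2 (-0.68, adjusted p = 0.198) and Meis2 (-0.33, adjusted p = 0.408) did not. Many blood genes fell: 10 of 17 primitive erythroid genes were lower and none higher, with the globin genes Hbb-y (-5.14 ± 0.75) and Hbb-bs (-4.14 ± 0.57) among them. Adjusted over the list alone, 10 were lower as well (camera adjusted p = 0.000158, adjusted p = 0.631 with an estimated correlation). Genes of the Hedgehog and ventral list were higher than in wt at 9.5 dpc, with 8 of 13 higher and 0 lower, and 9 higher when adjusted over the list alone (camera adjusted p = 0.00214, adjusted p = 0.631 with an estimated correlation). Shh was higher by 4.04 ± 0.66, Foxa2 was at least 38.1-fold higher, Foxa1 44.0-fold (95% interval 11.8 to 369) and Nkx2-9 12.5-fold (3.92 to 63.4). With wt replicate 2 left out, these were at least 10.3-fold, 7.90-fold and 3.36-fold, and without Skp1aKO replicate 2 Nkx2-9 was 7.22-fold higher. Shh had 9.42 and 11.9 CPM in the libraries labelled Skp1aKO and 1.10 and 0.41 CPM in wt at 9.5 dpc. It had 13.8 and 9.72 CPM in wt at 9.0 dpc and 11.7 and 16.9 CPM in wt PI. Foxa2, Foxa1 and Nkx2-9 were also higher in wt at 9.0 dpc and wt PI than in wt at 9.5 dpc. For these genes wt at 9.5 dpc was thus low among the wt groups.

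Hox genes, the best known Polycomb targets, were near 0 in wt. Of the 16 tested, 6 were higher in the libraries labelled Skp1aKO than in wt and 0 lower, and adjusted over the list alone 11 were higher (camera adjusted p = 0.000429, adjusted p = 0.631 with an estimated correlation). These 16 of 39 Hox genes passed the low-count filter, and a gene near 0 in wt could pass it only through libraries with a Skp1a label. The direction of the list was thus largely fixed by the filter, and the camera result does not test it. Hoxa7 was at least 5.87-fold, Hoxa9 at least 6.60-fold and Hoxd8 at least 4.77-fold higher, and Hoxb2 was 16.5-fold higher (95% interval 4.19 to 142). Hoxa9 stood at 1.95 ± 0.264 CPM. Against wt replicate 1 alone the bounds of Hoxa7, Hoxa9 and Hoxd8 were 1.58-fold, 1.78-fold and 1.28-fold, and Hoxb2 was 8.88-fold higher. The background rates were 7.14 and 9.31 times the lowest library here against 1.13 and 1.23 times in wt at 9.5 dpc. They stood at 0.685 and 0.892 CPM per kb of exon, scaled by library totals. Counts as low as those of Hoxa7, Hoxa9 and Hoxd8 cannot be told apart from such background. Of 33 proteasome subunits 18 were lower and 2 higher, and 23 and 2 adjusted over the list alone (camera adjusted p = 7.2e-06, adjusted p = 0.631 with an estimated correlation), with Psma1 (-2.88 ± 0.55) and Psmc6 (-2.62 ± 0.49) as examples. Of 19 genes of SCF ligases 9 were lower and 1 higher, and 10 and 1 adjusted over the list alone (camera adjusted p = 0.00369, adjusted p = 0.631 with an estimated correlation), among them the F-box gene Fbxo11 (-2.65 ± 0.37) and the scaffold Cul1 (-1.77 ± 0.40). Of 13 PRC2 genes 4 were lower and 2 higher under TMM, which turned to 1 lower and 4 higher with library totals. Adjusted over the list alone 4 were lower and 3 higher under TMM (camera adjusted p = 0.203). Rbbp7 (-1.96 ± 0.51) and Mtf2 (-1.69 ± 0.45) were lower and Ezh1, the second methyltransferase, was higher (1.22 ± 0.34). With library totals 11 proteasome subunits were lower and 2 higher, 7 SCF genes lower and 3 higher, 8 erythroid genes lower and 1 higher, and 10 Hedgehog and 11 Hox genes higher.

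Of all genes, 6852 were called between the libraries labelled Skp1aKO and wt, 3323 higher and 3529 lower. The median log2 fold change of all genes was 0.24 under TMM, 0.47 under DESeq2 size factors and 1.04 under library totals, and 48.5%, 52.7% and 83.0% of the called genes were higher. The largest bounded increases beside Foxa2 were those of Septin12 (at least 33.0-fold), Smok2b (31.2-fold), Exosc6 (25.7-fold), Ahnak2 (23.8-fold) and Cd1d2 (22.4-fold), all with 0 counts in wt at 9.5 dpc. Each of these genes also had more CPM in Skp1acont replicate 2, the library of highest background, than in Skp1acont replicate 1. Septin12 had 18.1 and 3.23 CPM in them. Part of these counts may thus be background. H3f3c, which resembles other histone H3 genes, had no count in any library with a Skp1a label and was at least 203-fold lower. Slc24a5, a pigment cell gene, was lower (log2 fold change -7.27 ± 1.33), Hbb-bt was 585-fold lower (95% interval 105 to 23130), the platelet factor Pf4 423-fold (117 to 3497), the placental hormone gene Prl8a2 218-fold (74.2 to 1058, with 104 ± 103 CPM in wt) and the myeloid adaptor Tyrobp 56.4-fold (9.75 to 2262). Prl8a2 had at most 2.37 CPM in wt at 9.0 dpc and wt PI, and Tyrobp at most 0.538 CPM. Pf4 had 0.346 and 0.119 CPM in wt at 9.0 dpc and 21.7 and 18.8 CPM in wt PI. High values of Prl8a2 and Tyrobp were thus particular to wt at 9.5 dpc. Against wt replicate 1 alone the bounded increases beside Foxa2 were at least 6.02-fold (Cd1d2) to 8.88-fold (Septin12). Leaving out Skp1aKO replicate 1 gave at least 100-fold for H3f3c, 95.9-fold for Hbb-bt and 9.25-fold for Tyrobp, and leaving out Skp1aKO replicate 2 gave at least 103-fold and ratios of 297 and 28.6. Prl8a2 was 97.9-fold lower without wt replicate 1 and 543-fold without wt replicate 2. The count of calls fell to 356 without Skp1aKO replicate 1, 857 without Skp1aKO replicate 2, 1716 without wt replicate 1 and 281 without wt replicate 2, and was 11548 without Skp1acont replicate 2. With the background subtracted it was 3713.

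The comparison of Skp1acont with wt at 9.5 dpc addresses how far the possible controls of the libraries labelled Skp1aKO differ. Skp1a (-2.34 ± 0.54, adjusted p = 0.0141), Ezh2 (-1.63 ± 0.47, adjusted p = 0.027), Eed (-1.70 ± 0.35, adjusted p = 0.0105) and Suz12 (-1.98 ± 0.54, adjusted p = 0.0226) were lower in Skp1acont, and Meis2 did not pass (-0.86 ± 0.36, adjusted p = 0.083). With library totals Skp1a (-1.65, adjusted p = 0.0224) and Eed (-0.98, adjusted p = 0.0306) stayed called and Ezh2 (-0.93, adjusted p = 0.0894) and Suz12 (-1.29, adjusted p = 0.0512) did not. Erythroid genes were lower again, 9 of 17 with 1 higher (camera adjusted p = 0.000683, adjusted p = 0.581 with an estimated correlation), with Hbb-bt at -4.86 ± 0.48. Of the 16 Hox genes 7 were higher and 0 lower, and 10 adjusted over the list alone (camera adjusted p = 0.000683, adjusted p = 0.581 with an estimated correlation), with Hoxa9 at least 10.6-fold, Hoxa7 7.08-fold, Hoxd8 5.11-fold and Hoxb3 4.33-fold higher. The low-count filter largely fixed this direction too. Leaving out Skp1acont replicate 2 brought Hoxa9 to 3.85-fold, Hoxd8 to 3.20-fold and Hoxb3 to 2.56-fold, leaving out Skp1acont replicate 1 to 21.4-fold, 8.14-fold and 7.13-fold, and against wt replicate 1 alone the bounds, with Hoxa7, ran from 1.16-fold to 2.86-fold. Of 33 proteasome subunits 12 were lower and 0 higher (camera adjusted p = 4.63e-05, adjusted p = 0.581 with an estimated correlation), among them Psma1 (-2.66 ± 0.54) and Psmc6 (-2.44 ± 0.48). Of 19 genes of SCF ligases 8 were lower and 1 higher, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.00429, adjusted p = 0.581 with an estimated correlation). Of 13 Hedgehog and ventral genes 4 were higher and 0 lower (camera adjusted p = 0.105). Of 13 PRC2 genes 6 were lower and 2 higher under TMM (camera adjusted p = 0.119), and 1 lower and 4 higher with library totals. Adjusted over the list alone, 6 PRC2 genes were lower and 2 higher, 12 proteasome subunits lower and 0 higher, and 9 erythroid genes lower and 1 higher. With library totals 6 proteasome subunits were lower and 2 higher, 8 erythroid genes lower and 1 higher, 4 SCF genes lower and 4 higher, and 10 Hox genes higher and 0 lower.

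In all, 6866 genes were called between Skp1acont and wt, 3642 higher and 3224 lower. The median log2 fold change was 0.34 under TMM, 0.62 under size factors and 1.08 under library totals, and 53%, 59.6% and 85.1% of the called genes were higher. Cd1d2 was at least 35.4-fold, Apol7b 30.7-fold, Septin12 30.3-fold, Smok2b 27.1-fold, Ttll6 22.0-fold and Parp10 18.1-fold higher, with 0 counts in wt. Prl8a2 was at least 203-fold, H3f3c 189-fold and Zfp969 26.3-fold lower, Zfp968 was 60.6-fold lower (95% interval 16.5 to 505) and the neuronal gene Lrrn3 26.3-fold (8.72 to 130). Prl8a2 (at most 2.37 CPM) and Lrrn3 (at most 1.94 CPM) were also low in wt at 9.0 dpc and wt PI. With Skp1acont replicate 2, the library of highest background, left out, the increases were at least 14.1-fold for Cd1d2 and Apol7b, 10.9-fold for Septin12, 9.61-fold for Smok2b, 8.97-fold for Parp10 and 3.85-fold for Ttll6, and with replicate 1 left out 32.6-fold (Parp10) to 69.2-fold (Cd1d2). Against wt replicate 1 alone they were 4.87-fold (Parp10) to 9.53-fold (Cd1d2). The decreases without Skp1acont replicate 1 were at least 78.4-fold for Prl8a2, 73.1-fold for H3f3c and 15.6-fold for Zfp968, and without replicate 2 they were 124-fold, 116-fold and 37.2-fold. Zfp969 and Lrrn3 were each 16.1-fold lower without Skp1acont replicate 2, Zfp969 as a bound, and each at least 10.15-fold without replicate 1, and Prl8a2 at least 91.2-fold without wt replicate 1 and 506-fold without wt replicate 2. The background rates were 3.10 and 14.6 times the lowest library in Skp1acont. The bounded increases were larger in the library of higher rate, so part of them may be background. The number of genes called was 0 when only these groups were fitted, with 4271 at an unadjusted p under 0.05, and DESeq2 called 6991. It was 13512 without Skp1acont replicate 1, 519 without wt replicate 1 and 13 without wt replicate 2.

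The change with stage in wild type was taken from wt at 9.5 dpc against wt at 9.0 dpc. Most genes of the neuronal differentiation list rose. Doublecortin (Dcx), a microtubule gene of young neurons, went from 0.998 ± 0.433 to 42.2 ± 6.71 CPM (n = 2 each, log2 fold change 5.23 ± 0.48, adjusted p = 0.00291), the neurofilament gene Nefm from 5.85 ± 0.444 to 75.7 ± 3.45 CPM (3.68 ± 0.35, adjusted p = 0.00291) and the RNA-binding gene Elavl3 from 1.28 ± 0.140 to 20.5 ± 5.27 CPM (3.99 ± 0.43, adjusted p = 0.0039). Of the 34 tested genes of this list 21 rose and 0 fell, and 27 rose when adjusted over the list alone (camera adjusted p = 4.7e-34, adjusted p = 0.111 with an estimated correlation). The transcription factor gene Nhlh2 rose by 6.44 ± 0.64, Neurod1 was 104-fold higher (95% interval 35.4 to 510) and the peptide gene Sst 785-fold (140 to 31044). Some genes of the Hedgehog and ventral list fell: Foxa2 was at least 39.0-fold lower, Foxa1 54.0-fold (14.6 to 451) and Nkx2-9 29.8-fold (9.90 to 147), and Shh changed by -4.17 ± 0.66 (adjusted p = 0.0158). Without wt 9.5 dpc replicate 2 the decreases were at least 10.5-fold for Foxa2, 9.70-fold for Foxa1 and 8.02-fold for Nkx2-9, and without wt 9.0 dpc replicate 2 the increases were at least 26.7-fold for Neurod1 and 66.8-fold for Sst. Of the 13 genes of that list 4 fell and 0 rose, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.41e-06, adjusted p = 0.126 with an estimated correlation). Of 7 endoderm and yolk sac genes, a list that also holds Foxa1, 2 fell and 0 rose (camera adjusted p = 0.0104, adjusted p = 0.424 with an estimated correlation).

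The neural progenitor list moved both ways with stage. The intermediate filament gene Nes rose from 20 ± 0.389 to 81.5 ± 12.5 CPM and Notch1 from 18.8 ± 0.379 to 47.0 ± 4.67 CPM, and Lin28a, a regulator of early developmental timing, fell from 85.3 ± 11.1 to 16.2 ± 1.70 CPM. Over all genes 2 of 16 rose and 1 fell, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.00182, adjusted p = 0.587 with an estimated correlation). Of 12 Notch targets 3 rose and 0 fell, Nrarp (2.02 ± 0.33), Hes6 (1.96 ± 0.41) and Notch1, and 5 rose adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.452 with an estimated correlation). With the lot as a block Notch1 (adjusted p = 0.0655) and Hes6 (adjusted p = 0.0515) were past the threshold no longer. Among 26 genes of the midbrain and isthmus, Zic1 (37.8 ± 0.835 to 211 ± 3.14 CPM) and Cnpy1 (17.8 ± 0.232 to 121 ± 4.40 CPM) rose and Foxa2 fell, and 10 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0764). Of 12 surface ectoderm genes 5 fell and 0 rose, and 8 fell adjusted over the list alone, including the keratins Krt18 (100 ± 8.80 to 6.87 ± 3.48 CPM) and Krt8 (78.5 ± 2.44 to 8.34 ± 1.41 CPM) and Epcam. Camera gave adjusted p = 3.46e-09, and adjusted p = 0.0397 with an estimated correlation, the only list of this comparison to stay called, and adjusted p = 0.0932 with the lot as a block. Among 40 Polycomb-target regulators Lhx9 rose (4.54 ± 0.39) and 5 fell, with Foxc2 (-4.39 ± 0.60) as an example, and 2 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.000377, adjusted p = 0.424 with an estimated correlation). The macrophage genes Fcer1g (3.75 ± 0.67) and Tyrobp (34.7-fold, 95% interval 9.21 to 293) rose, 2 of 8, and 4 adjusted over the list alone (camera adjusted p = 4.85e-06, adjusted p = 0.105 with an estimated correlation). The platelet genes Pf4 (521-fold, 144 to 4305) and Ppbp (at least 20.9-fold) were also higher. Leaving out wt 9.0 dpc replicate 2 gave 266-fold for Pf4 and at least 5.33-fold for Ppbp and 5.90-fold for Tyrobp.

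Over all genes 302 were called between the stages, 239 higher and 63 lower at 9.5 dpc, and DESeq2 called 538. Higher genes made up 79.1% of the calls under TMM and 87.6% with library totals, and the median log2 fold change was -0.03 and 0.08. The fit of the 6 wt libraries, added after the data were seen, called 4161 genes, 1963 higher and 2198 lower, among them 300 of the 302, and 5469 with the lot as a block. On simulated counts the fit of the wt libraries, without the block, made a larger share of false calls than the threshold allows. Calls of the planned fit were 0 without wt 9.0 dpc replicate 1, 0 without wt 9.0 dpc replicate 2, 29 without wt 9.5 dpc replicate 1, 44 without wt 9.5 dpc replicate 2 and 3008 without Skp1acont replicate 2. Other large decreases were those of Spink1 (42.6-fold, 14.3 to 209), the haemangioblast factor Etv2 (34.2-fold, 11.4 to 168), the retinoic acid hydroxylase Cyp26a1 (24.7-fold, 8.17 to 122), Apela (at least 20.5-fold) and Hmga1b (at least 15.5-fold). Leaving out wt 9.5 dpc replicate 2 gave 17.2-fold for Spink1, at least 5.53-fold for Apela and at least 4.17-fold for Hmga1b. Spink1 was 93.3-fold lower without wt 9.5 dpc replicate 1, and Hmga1b at least 26.8-fold without wt 9.0 dpc replicate 2. In the fit of the wt libraries more lists showed called members, and no list kept its camera call with an estimated correlation. Of 18 cholesterol synthesis genes 14 rose and 0 fell, with Hmgcs1 from 284 ± 6.22 to 736 ± 80.9 CPM and Cyp51 from 64.0 ± 2.39 to 149 ± 17.8 CPM, and the same adjusted over the list alone (camera adjusted p = 3.16e-05, adjusted p = 0.366 with an estimated correlation). Fabp7, a radial glia gene, rose from 105 ± 8.21 to 1080 ± 43.9 CPM (3.4 ± 0.11, adjusted p = 2.87e-07). Proteasome subunits fell, 22 of 33 with 0 risen and 28 adjusted over the list alone (camera adjusted p = 2.88e-06, adjusted p = 0.577 with an estimated correlation), Psmc5 among them (224 ± 18.7 to 125 ± 23.5 CPM). Of 21 hypoxia and glycolysis genes 12 fell and 0 rose, with Hk2 (97.1 ± 7.95 to 39.5 ± 4.38 CPM) and Slc2a3 (313 ± 5.75 to 46.5 ± 12.8 CPM) as examples, and 12 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000271, adjusted p = 0.366 with an estimated correlation). Of 16 erythroid genes 8 rose and 1 fell, with Hbb-y at 2.27 ± 0.16, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.0079, adjusted p = 0.366 with an estimated correlation). Of 11 PRC2 genes 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.414), with Aebp2 (1.04 ± 0.10), Suz12 (0.67 ± 0.11) and Ezh2 (0.40 ± 0.10) higher and Rbbp7 (-0.59 ± 0.09) lower. Skp1a differed by -0.27 ± 0.11 (adjusted p = 0.0873), and passed with the lot as a block (adjusted p = 0.0159). Meis2 rose by 1.38 ± 0.10 (adjusted p = 1.57e-05) in this fit and was not called in the planned fit (1.34 ± 0.37, adjusted p = 0.135).

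**Figure D3:**
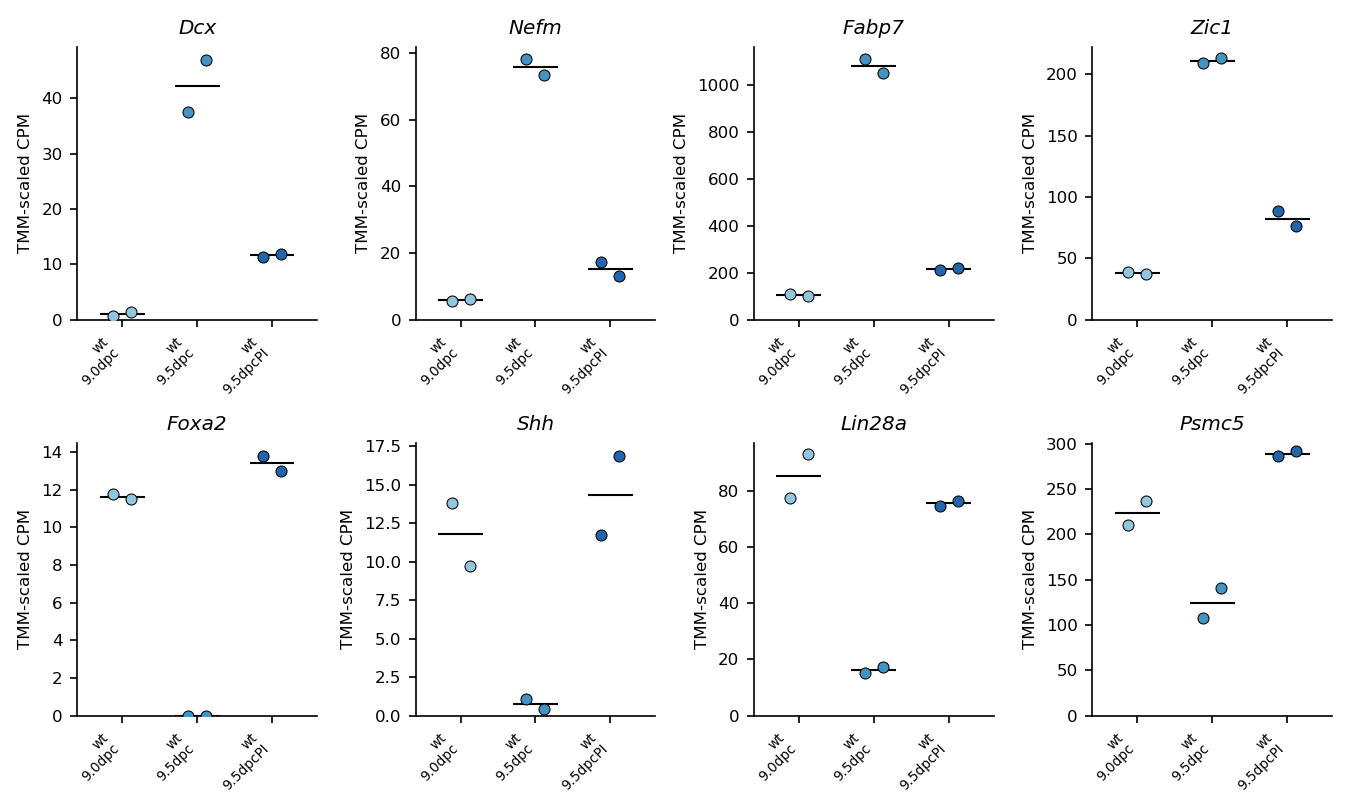
TMM-scaled CPM of Dcx, Nefm, Fabp7, Zic1, Foxa2, Shh, Lin28a and Psmc5 in each library (points) of wt at 9.0 dpc, wt at 9.5 dpc and wt PI at 9.5 dpc. Dcx averages 0.998, 42.2 and 11.7 CPM in these groups and Lin28a 85.3, 16.2 and 75.6 CPM.

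The comparison of wt PI with wt at 9.5 dpc addresses what the condition named PI changes in wild type. Some genes of the Hedgehog and ventral list were higher with PI. Foxa2 had 0 counts in wt at 9.5 dpc and 13.4 ± 0.549 CPM in wt PI (n = 2 each, at least 44.5-fold), Foxa1 was 64.7-fold higher (95% interval 17.6 to 539) and Nkx2-9 63.3-fold (21.4 to 309). The floor plate gene Spon1 rose from 6.80 ± 0.245 to 35.4 ± 0.779 CPM (log2 fold change 2.38 ± 0.33, adjusted p = 0.0483). Of the 13 Hedgehog and ventral genes 3 rose and 0 fell, and 6 rose adjusted over the list alone (camera adjusted p = 2.52e-10, adjusted p = 0.134 with an estimated correlation). The endoderm and yolk sac list, which also holds Foxa1, had 2 of 7 higher and 0 lower (camera adjusted p = 0.0365, adjusted p = 0.708 with an estimated correlation). Camera did not call it with the lot as a block. The wt 9.5 dpc group was the only one with 0 counts of Foxa2, which had 11.8 and 11.5 CPM in wt at 9.0 dpc. A few genes of neurons were lower: Nefm fell from 75.7 ± 3.45 to 15.2 ± 2.91 CPM (-2.33 ± 0.32, adjusted p = 0.0468) and Mapt, encoding tau, from 12.5 ± 0.521 to 1.83 ± 0.150 CPM (-2.73 ± 0.37, adjusted p = 0.0401). Of 34 neuronal differentiation genes 2 fell and 0 rose, and 17 fell and 2 rose adjusted over the list alone (camera adjusted p = 2.97e-11, adjusted p = 0.708 with an estimated correlation). Shox2 (28.2 ± 0.639 to 2.28 ± 0.185 CPM), Lhx9 (34.3 ± 5.02 to 6.16 ± 0.419 CPM), Epha4 (45.4 ± 1.78 to 10.8 ± 0.2 CPM) and Pdzrn4 (12 ± 0.149 to 1.50 ± 0.166 CPM) also fell. With the lot as a block Spon1 (adjusted p = 0.0757), Mapt (0.0562), Lhx9 (0.0514) and Pdzrn4 (0.0501) did not pass. Spink1 was 104-fold higher (35.4 to 508) and Hbb-bh0 46.7-fold (15.7 to 229). Against wt replicate 1 alone Foxa2 was at least 12-fold, Foxa1 11.6-fold and Nkx2-9 17-fold higher, and Spink1 42.1-fold, against 228-fold with wt replicate 2 alone.

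The planned fit called 13 genes with PI in wt, 7 higher and 6 lower, and DESeq2 called 218. The fit of the 6 wt libraries, whose share of false calls on simulated counts exceeded the threshold, called 3669, 2042 higher and 1627 lower, and held all 13. With the lot as a block it was 5111. Calls of the planned fit were 0 without wt replicate 1, 1 without wt replicate 2, 0 without wt PI replicate 1, 0 without wt PI replicate 2 and 2361 without Skp1acont replicate 2. With the background subtracted the planned fit called 0. The background rates were 1.28 and 1.75 times the lowest library in wt PI and 1.13 and 1.23 times in wt at 9.5 dpc. Higher genes made up 53.8% of the calls under TMM and 44.4% with library totals.

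In the fit of the wt libraries camera called several lists with PI, and no list kept its call with an estimated correlation. Of 33 proteasome subunits 24 rose and 0 fell, and 28 rose adjusted over the list alone, with Psmc5 from 125 ± 23.5 to 289 ± 3.50 CPM (1.21 ± 0.12, adjusted p = 0.00024) and Psmd13 from 29.3 ± 8.80 to 80.4 ± 9.90 CPM as examples (camera adjusted p = 1.61e-08, adjusted p = 0.515 with an estimated correlation). Of 21 hypoxia and glycolysis genes 15 rose and 0 fell, and 16 rose adjusted over the list alone, with Hk2 at 1.38 ± 0.12 and Pfkfb3 at 1.24 ± 0.19 (camera adjusted p = 9.09e-07, adjusted p = 0.478 with an estimated correlation). Of 17 NRF2 genes 10 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.00371, adjusted p = 0.507 with an estimated correlation). The pentose phosphate genes Tkt (0.96 ± 0.13), G6pdx (0.81 ± 0.14) and Pgd (0.59 ± 0.12) rose, and the glutathione synthesis gene Gclm fell (-0.50 ± 0.11). Of 19 heat shock genes 5 rose and 2 fell, and 5 and 3 adjusted over the list alone (camera adjusted p = 0.633), 7 and 4 with the lot as a block, with the HSP90 co-chaperones Stip1 (1.52 ± 0.12) and Ahsa1 (1.17 ± 0.14) higher and Hspa4l (-1.12 ± 0.11) lower. Of 31 neuronal genes 24 fell and 2 rose, and 25 and 2 adjusted over the list alone (camera adjusted p = 9.27e-11, adjusted p = 0.507 with an estimated correlation), among them Dcx (-1.86 ± 0.17). Of 11 Hedgehog and ventral genes 6 rose and 0 fell, also adjusted over the list alone, with Shh at 4.55 ± 0.44 (camera adjusted p = 0.00186, adjusted p = 0.478 with an estimated correlation). Of 23 midbrain genes 8 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.775), with Pax5 at 1.48 ± 0.16 and Zic1 at -1.37 ± 0.10.

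Some Polycomb genes and blood genes were called with PI in the same fit, and camera called neither the PRC2 nor the Polycomb-target list. Of 11 PRC2 genes 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.633). Suz12 (-0.58 ± 0.11, adjusted p = 0.00373), Ezh2 (-0.55 ± 0.10, adjusted p = 0.00285) and the cofactor gene Lcor (-0.71 ± 0.16) fell and Rbbp7 (0.58 ± 0.09) rose, while Eed (0.12 ± 0.10, adjusted p = 0.421) and Skp1a (0.23 ± 0.11, adjusted p = 0.142) did not pass. With the lot as a block Skp1a was higher (0.24 ± 0.09, adjusted p = 0.0374). Of 25 Polycomb-target regulators 1 rose and 4 fell, Isl1 (-1.53 ± 0.15) and Foxc1 (-0.87 ± 0.18) among the latter, and 0 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.471). With the lot as a block 3 rose and 5 fell. Meis2 fell by 1.04 on the log2 scale, from 190 ± 9.60 to 93.5 ± 1.04 CPM (adjusted p = 0.000203). Of 16 erythroid genes 5 fell and 0 rose, and 6 fell adjusted over the list alone, with Hbb-bt (-2.64 ± 0.16) and Hbb-bh1 (-1.26 ± 0.15) as examples (camera adjusted p = 0.00632, adjusted p = 0.507 with an estimated correlation). With the lot as a block 9 erythroid genes fell and 1 rose. Of 5 macrophage genes 3 fell, Csf1r (-4.46 ± 0.96), Tyrobp (-3.66 ± 0.54) and Fcer1g (-1.96 ± 0.44), and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0264, adjusted p = 0.507 with an estimated correlation). Other large decreases were those of Lhx2 (-4.66 ± 0.71), the sodium channel gene Scn9a (-3.47 ± 0.56) and the Notch ligand gene Dner (-3.31 ± 0.34).

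**Figure D4:**
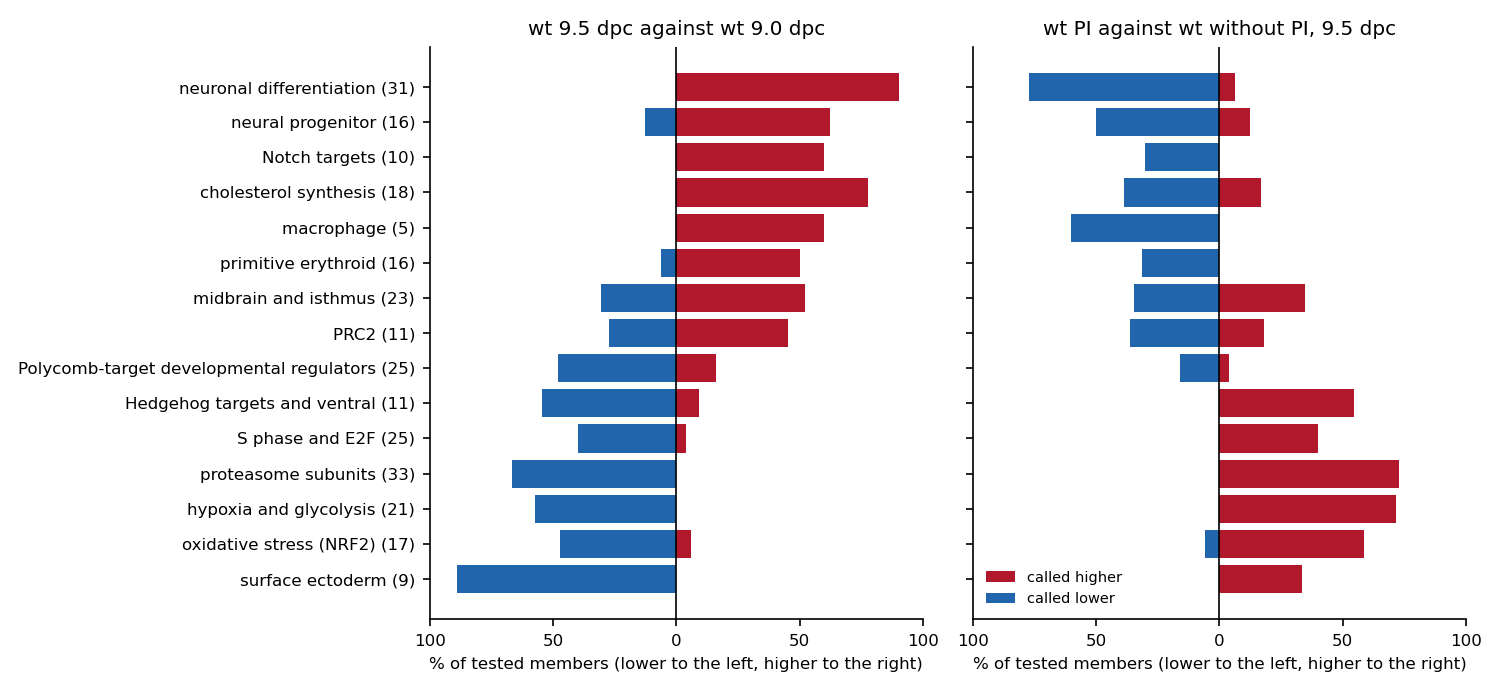
Share of the tested genes of 15 lists called higher (right) or lower (left) in the fit of the 6 wt libraries, in %, for wt at 9.5 dpc against 9.0 dpc and for wt PI against wt at 9.5 dpc. Of the neuronal differentiation genes 28 of 31 were higher with stage and 24 of 31 lower with PI.

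The comparison of Skp1acont PI with Skp1acont asks the same of PI in Skp1acont, with 1 library on the PI side. Nkx2-9 had 13.9 CPM with PI and 1.13 ± 0.530 CPM without (log2 difference 3.66 ± 0.62), Foxa1 7.83 and 1.17 ± 0.0476 CPM, and the Hedgehog receptor gene Ptch1 111 and 41.5 ± 12.6 CPM. Shox2 had 2.15 and 10 ± 1.39 CPM and Zfp105 4.30 and 14 ± 0.224 CPM. Each of these had an adjusted p of 0.80. No gene was called in edgeR, with 867 at an unadjusted p under 0.05, and DESeq2 also called 0. Of 13 Hedgehog and ventral genes 0 passed over all genes, and 6 were higher adjusted over the list alone (camera adjusted p = 8.03e-07, adjusted p = 0.306 with an estimated correlation). Of 33 proteasome subunits 0 passed (camera upward, adjusted p = 6.76e-05, adjusted p = 0.657 with an estimated correlation), and without Skp1acont replicate 2 the direction turned (adjusted p = 0.079). Skp1a differed by 0.43 ± 0.62, Ezh2 by 0.33 ± 0.56 and Suz12 by 0.54 ± 0.63. Without Skp1acont replicate 2, 14 genes were called, 5 higher and 9 lower, and without Skp1acont replicate 1 it was 9239. Both fits set 1 library against 1, with the spread borrowed from the other groups, so these calls do not test PI. The median log2 difference of all genes was -0.12 under TMM, -0.26 under size factors and -0.23 under library totals.

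Whether PI acted differently in Skp1acont and wt was tested directly as the difference of the PI effects. With predicted genes and genes under 5 CPM set aside, the smallest p-values were those of Ppbp and Hbb-bh0. Ppbp had 6.07 CPM in Skp1acont PI, 0.190 ± 0.269 CPM in Skp1acont, 5.41 ± 0.383 CPM in wt and 0 counts in wt PI (adjusted p = 0.338). Hbb-bh0 had 0.587, 1.17 ± 0.0476, 0.319 ± 0.0683 and 13.5 ± 1.02 CPM in these groups (adjusted p = 0.338). Slc51a (3.44 ± 0.60), Renbp (-3.18 ± 0.58) and Epha4 (1.96 ± 0.37) followed with adjusted p from 0.711 to 0.75. No gene passed in edgeR, 1198 had an unadjusted p under 0.05 and DESeq2 called 5. Of 34 neuronal differentiation genes 0 passed over all genes and 3 were higher adjusted over the list alone (camera upward, adjusted p = 1.96e-06, adjusted p = 0.691 with an estimated correlation). Of 17 erythroid genes 0 passed, and 1 adjusted over the list alone (camera upward, adjusted p = 1.96e-06, adjusted p = 0.572 with an estimated correlation). There were 452 calls without Skp1acont replicate 2, 130 higher and 322 lower, and without Skp1acont replicate 1 it was 6507.

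Directions were compared between pairs of comparisons that share no library. Of the 13 genes called with PI in wt, 92.3% had the same direction with PI in Skp1acont (fry p = 0.00198), while the correlation of log2 fold changes across all 18837 genes was -0.04, so the test and the correlation differed in sign. Leaving out a library also changed which genes were called and entered the fry test. Without Skp1acont replicate 2 the fry p was 0.953 over 2361 genes, and without wt PI replicate 2 the correlation was 0.141. Of the 302 genes called between stages, 37.1% had the same direction in the libraries labelled Skp1aKO against Skp1acont (r = 0.01, fry p = 0.131) and 38.1% with PI in Skp1acont (r = 0.004, fry p = 0.24). The former was past the threshold without Skp1aKO replicate 1 (150 genes, p = 0.0259), Skp1acont replicate 1 (3763 genes, r = -0.01, p = 0.0297) or Skp1acont replicate 2 (3008 genes, r = -0.002, p = 0.0412), and the latter without Skp1acont replicate 1 (3763 genes, r = -0.01, p = 0.00253). The differences between the libraries labelled Skp1aKO and wt went against those of PI in Skp1acont, with r = -0.42 and 22.7% of 6852 genes in the same direction (fry p = 0.413). This turned to r = 0.16 without Skp1acont replicate 2 (p = 0.0487 over 11548 genes) and stood at r = -0.60 without Skp1acont replicate 1 (p = 1.06e-05 over 12475 genes). For the libraries labelled Skp1aKO against Skp1acont and PI in wt, r was -0.04 and no gene was called in the former.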

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

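Each comparison was repeated with the alternatives fixed beforehand, with alternatives added after the data were seen and with 1 library left out at a time. The alternatives added later were the background rate as a covariate, background subtraction, library totals, the fits of the wt libraries, and leaving out Skp1acont replicate 2 where a comparison does not use it. Skp1acont PI has 1 library and could not be left out. Ranges cover the libraries of the groups compared and Skp1acont replicate 2. Outside them, without Skp1acont replicate 1, 12475 genes were called for Skp1aKO against wt, 3181 for PI in wt and 3763 for stage, and for stage 150 and 158 without Skp1aKO replicate 1 and 2.

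For the libraries labelled Skp1aKO against Skp1acont, 0 genes were called in the planned fit. The count was 1 with DESeq2 size factors in edgeR, 5 without a low-count filter, 1239 with the background rate as a covariate, 4 with library totals and 95 with the DESeq2 test. Leaving out 1 library gave 0 to 5723 calls, the highest without Skp1acont replicate 1, with 4650 without Skp1acont replicate 2. The result of 0 genes did not hold. The closing part weighs the 4650, and the cause of the other counts was not tested.

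For the libraries labelled Skp1aKO against wt, 6852 genes were called, 1897 with the background rate as a covariate and 3713 with the background subtracted. With 1 library left out there were 281 to 11548 calls, the lowest without wt replicate 2 and the highest without Skp1acont replicate 2. It was 356 without Skp1aKO replicate 1, 857 without Skp1aKO replicate 2 and 1716 without wt replicate 1. With the background covariate Ezh2 turned to 0.14 and Prl8a2 to 10.18 on the log2 scale, neither past the threshold. The number did not hold, and the cause was not tested.

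For Skp1acont against wt, 6866 genes were called, 2040 with the background covariate, 4024 with the background subtracted and 0 with only the groups compared in the fit. Between 13 and 13512 genes were called with 1 library left out, the lowest without wt replicate 2 and the highest without Skp1acont replicate 1, with 519 without wt replicate 1. This number did not hold, and the cause was not tested.

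For PI in Skp1acont 0 genes were called, 5 with the background covariate and 1 with only the groups compared. Without Skp1acont replicate 2 there were 14 and without replicate 1 there were 9239. For the difference of the PI effects 0 genes were called, 1 without a low-count filter, 60 with the background covariate and 5 with DESeq2. With 1 library left out it was 0 to 6507, the highest without Skp1acont replicate 1, with 452 without Skp1acont replicate 2. Neither 0 held, and the cause was not tested.

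For PI in wt 13 genes were called, 27 without a low-count filter, 2378 with the background covariate, 0 with the background subtracted, 218 with DESeq2 and 3397 with only the groups compared. The wt libraries alone gave 3669. Leaving out 1 library gave 0 to 2361 calls, the highest without Skp1acont replicate 2, 0 without wt replicate 1 or either wt PI library, and 1 without wt replicate 2. For stage in wt 302 genes were called, 2179 with the background covariate, 143 with the background subtracted, 538 with DESeq2, 3309 with only the groups compared and 4161 from the wt libraries alone. Leaving out 1 library gave 0 to 3008 calls, 0 without either wt 9.0 dpc library, 29 and 44 without wt 9.5 dpc replicate 1 and 2, and 3008 without Skp1acont replicate 2. Neither number held. The biological coefficient of variation was 35.3% in the planned fit, 19.4% without Skp1acont replicate 2 and 19.6% in the wt libraries alone. The spread between the Skp1acont libraries, which neither comparison uses, thus held the calls of the planned fit down. Leaving out a wt library left 1 library in a compared group. The cause of the other counts was not tested.

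With replicate as a block the libraries labelled Skp1aKO against Skp1acont gave 1 gene in place of 0. In the wt libraries alone the block gave 5111 genes for PI and 5469 for stage. The correlation of the stage effect with PI in Skp1acont was -0.0107 with the block and 0.00414 without. Of the named genes Spon1, Pdzrn4, Mapt and Lhx9 for PI and Notch1, Hes6 and Slc2a3 (adjusted p = 0.0503) for stage were not called with the block in the fit of all groups. In the wt libraries alone Skp1a in both comparisons and Pax9 (adjusted p = 0.0394) and Hemgn (adjusted p = 0.0488) for PI were called only with the block. Among the lists described, surface ectoderm with an estimated correlation and S phase genes (camera adjusted p = 0.0654), both for stage, were not called with it. The same held for the endoderm and yolk sac list for PI in wt, by camera in the fit of all groups. Camera calls of lists not described there changed too, such as SCF genes for PI in Skp1acont (adjusted p = 0.0872) and Hox genes for the PI difference (0.073).

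The correlation of Skp1aKO against Skp1acont with PI in wt was -0.0366, and -0.0125 without a low-count filter. With 1 library left out it was -0.0544 to 0.0101. For the libraries labelled Skp1aKO against wt and PI in Skp1acont it was -0.421, and -0.599 to 0.158 with 1 library left out, reversed without Skp1acont replicate 2. For PI in wt and in Skp1acont it was -0.0383, and -0.143 to 0.141, reversed without wt PI replicate 2 and with fry p = 0.953 without Skp1acont replicate 2 (r = -0.000972), where 2361 genes in place of 13 entered the test. Without wt replicate 1 (r = -0.0548), wt replicate 2 (r = -0.143) or wt PI replicate 1 (r = -0.0458) too few genes were called for the test. For stage and the libraries labelled Skp1aKO against Skp1acont it was 0.0132, and -0.0137 to 0.0339, at -0.0137 without Skp1acont replicate 1, -0.00200 without Skp1acont replicate 2 and 0.00320 without Skp1aKO replicate 1. For stage and PI in Skp1acont it was 0.00414, -0.0329 with at least 1 CPM in at least 4 libraries, and -0.116 to 0.111 with 1 library left out, reversed without Skp1acont replicate 1 (-0.0126). These directions did not hold, and the cause was not tested.

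Of 4202 values of named genes under the alternatives, 3170 stayed on their side of the threshold, called or not, 443 lost a call, 587 gained one and 2 reversed. Of the 3170, 32 changed sign.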

Other observations

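The fit of the 6 wt libraries, the medians by lot and the tests of a few dominant genes, genotype, ventral tissue and blood cells in this part were chosen after the results were seen. Some genes of DNA replication fell with stage and rose with PI in that fit, and these comparisons share the wt 9.5 dpc libraries. The median log2 difference of the S phase and E2F list was -0.16 for stage in lot 1 and 0.27 for PI in lot 2, and -0.23 for stage in lot 2 and 0.27 for PI in lot 1. The chromatin assembly gene Chaf1b changed by -1.22 ± 0.17 with stage and 1.86 ± 0.17 with PI on the log2 scale, and the cyclin gene Ccne1 by -0.80 ± 0.15 and 0.83 ± 0.15 (n = 2 per group). Of 25 S phase and E2F genes 10 fell and 1 rose with stage, also adjusted over the list alone (camera adjusted p = 0.0415, adjusted p = 0.366 with an estimated correlation, and camera adjusted p = 0.0654 with the lot as a block). With PI 10 rose and 0 fell, and 11 rose adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.507 with an estimated correlation), with the replicative helicase gene Mcm5 at 0.72 ± 0.11. Of 19 p53 targets 7 rose and 3 fell with stage, also adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.366 with an estimated correlation). Among them the antiproliferative gene Btg2 rose by 2.14 ± 0.13, Ccng1 by 1.35 ± 0.10 and Trp53inp1 by 1.80 ± 0.17, and Tnfrsf10b fell (-1.23 ± 0.31).

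Some neural progenitor genes were called with PI in the fit of the wt libraries, and the list was not. Lin28a rose from 16.2 ± 1.70 to 75.6 ± 1.10 CPM, and Fabp7 fell from 1080 ± 43.9 to 215 ± 5.51 CPM, Nes from 81.5 ± 12.5 to 29.7 ± 0.843 CPM and Notch1 from 47.0 ± 4.67 to 24.1 ± 0.991 CPM. Of 16 genes 8 fell and 2 rose, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0616). Of 21 genes of the unfolded protein and ATF4 response 10 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.372). Between wt PI and wt at 9.0 dpc 2046 genes were called, 1129 higher and 917 lower in wt PI, with Cnpy1 at 123 ± 13.1 against 17.8 ± 0.232 CPM and Krt18 at 16.9 ± 1.42 against 100 ± 8.80 CPM.

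Skp1a-labelled and wt libraries at 9.5 dpc differed in many genes, 6852 for the libraries labelled Skp1aKO and 6866 for Skp1acont. A few genes taking most of the counts are argued against as the whole cause, since one common factor moves all other genes alike and 3057 genes called between the libraries labelled Skp1aKO and wt lay over 2-fold above the median of all genes and 3513 below. Reads that do not come from spliced transcripts cannot be told apart from a real difference: after background subtraction 42.3% of the genes called higher in Skp1acont stayed called higher, between the bounds set beforehand. The filter removed 931 of the others, and 1169 lost the call. The median standard error of these 1169 rose from 0.82 to 1.71 and their median log2 fold change from 2.80 to 4.29. This decides nothing, since subtraction also takes low wt counts to 0. Genotype or line of the Skp1a-labelled embryos cannot be told apart from these reads either, because 0 wt libraries had a background rate inside the range of the Skp1a-labelled libraries.

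With Skp1acont replicate 2 left out, the libraries labelled Skp1aKO differed from Skp1acont replicate 1 in 4650 genes, among them Foxd1 and Foxc2. The axis that separates the Skp1acont libraries from each other fits this pattern, since the libraries labelled Skp1aKO minus Skp1acont PI correlated across genes with Skp1acont replicate 2 minus replicate 1 (r = 0.646). A difference between libraries that share the label Skp1acont is consistent with a technical source for part of the 4650, and the genotype stays open as untested apart from it.

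In the wt libraries the PI samples deviated from 9.5 dpc towards 9.0 dpc. Of the genes called in both comparisons, 985 were higher at 9.5 dpc and lower with PI, and 1299 lower at 9.5 dpc and higher with PI. Independent lists would give 243 and 342, but these comparisons share the wt 9.5 dpc libraries. Sharing the wt 9.5 dpc libraries alone gave r = -0.500 in simulations against -0.652 observed. The simulated value follows from the shared group by construction, so the gap between these values does not measure movement towards 9.0 dpc. With stage from one lot and PI from the other, r was -0.496 and -0.476. This argues against noise of single shared libraries as the whole cause. It does not exclude a deviation common to both wt 9.5 dpc libraries, which enters both differences. More ventral tissue as the whole cause does not account for proteasome subunits, whose median PI difference was 0.62 in lot 1 and 0.40 in lot 2, and fewer blood cells do not account for neuronal genes, whose medians were -1.24 and -1.16. For the ventral genes themselves more ventral tissue cannot be told apart from regulation, since 2 of 7 dorsal genes fell (Zic1 and Pax3) and Wnt1 rose. More endoderm in the sampled tissue was not tested, and the part of the embryo sampled is not known. A lag of the PI embryos in development could fit part of the rest, as a hypothesis that these labels do not test. Somite counts of PI and other embryos at collection would help to decide it. Other genes went otherwise: Cnpy1 had 114 and 133 CPM in wt PI, near wt at 9.5 dpc (124 and 118 CPM). Hbb-bh0 had 12.8 and 14.2 CPM in wt PI and at most 1.04 CPM in wt at either stage. A lag cannot be told apart here from other effects of PI or from a deviation of the wt 9.5 dpc libraries.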
